A study of Arabidopsis thaliana with 22 samples.

How the data were processed

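Leaf transcripts of 4 Arabidopsis thaliana lines were measured on 22 Affymetrix ATH1 arrays, which carry 1 short-oligonucleotide probe set or more for most genes of this plant. Per the labels, the lines were Columbia wild type (WT), a vector control (C2) and 2 independent lines (T6 and T8) that carry an InsP 5-ptase transgene, an enzyme that removes a phosphate from inositol phosphates. Each line was sampled on day 0 (well watered) and on day 7 without water. WT, T6 and T8 had 3 arrays at each time and C2 had 2, with leaves of about 10 plants pooled for each array.

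Per the labels' protocols, RNA was isolated with a spin-column kit and amplified through a two-cycle biotin labelling procedure, in which a second round of amplification strengthens the bias toward the 3' end of transcripts. The deposited values are MAS5 signals, per the submitters' processing notes, which is a linear probe set intensity. The MAS5 version, masks and detection calls are not given in the sources used here. The deposited intensity table holds 22810 probe sets, of which 64 are array controls. The trimmed mean signal, leaving out 2% of values at each end, lay between 495.3 and 496.6 on every array, a ratio of 1.0026 between the highest and the lowest, so the arrays carry a common scale and no further scaling was applied. Identical values at most probe sets were found in 0 pairs of arrays, and 0 columns of other samples were in the table.

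Signals were transformed as log2(signal + 16) without the control probe sets, so that a fold change of a dim probe set is understated. Without detection calls no background level is known. For a named gene with every array of the dimmer side below its own 40th percentile, a bound was taken after the data were seen, from log2 signals with each value below that percentile set to it. A probe set was kept when its signal reached its array's 40th percentile on at least 3 of the 22 arrays, which left 15808 of 22746. Linear models with 1 mean per group were fitted to all 22 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with 14 residual and 5.39 prior degrees of freedom. Benjamini-Hochberg adjustment was applied per comparison over the probe sets kept, and an adjusted p under 0.05 counted as a call. All adjusted p-values of single genes come from this limma fit. The 12 comparisons were the day 7 change in each of the 4 lines, the mean of T6 and T8 against WT at each time, the difference between their day 7 changes, the same 3 comparisons for C2 against WT, and T6 against T8 at each time. Each log2 difference is given with its standard error (SE), and group means with the standard deviation (SD) over arrays.

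A further test asked how far probe sets called in the C2 day 7 change moved in the other lines. Each change was multiplied by its sign in C2, the median over those probe sets was taken for each pair of arrays of the same number in a line, and T6 and T8 were set against WT with a two-sided exact permutation test. No C2 array enters those medians. The number joins a day 0 and a day 7 array that are not known to belong together, so the spread over pairs depends on this choice.

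Probe sets were named through the platform annotation and, through its gene identifiers, the TAIR10.1 gene table, which was used for names only. Of the 22746 probe sets, 13513 had 1 listed gene, 503 had several and 8730 had none listed; a probe set of the last 2 kinds stays unnamed here. After the filter 8655 genes had 1 name, each represented by its brightest probe set. Before the data were examined, 23 gene lists with 344 genes were fixed, of which 48 genes had a named probe set and 45 were measured after the filter. Lists with at least 3 named members (LEA proteins and dehydrins, heat shock, photosynthesis, phosphoinositide, senescence, flavonoid and cell wall) were tested with camera at an inter-gene correlation of 0.01 and again with an estimated correlation, with adjustment over the 7 lists. The estimate ran from 0.096 for phosphoinositide to 0.97 for flavonoid genes. A second test, fry, takes the members on their own without ranking them against other genes. It was fixed beforehand, and its directional results are given in part, with the flagged results and the processing alternatives. For abscisic acid metabolism, its receptors, phosphatases and transcription factors, DREB and CBF factors, raffinose, aquaporins, antioxidants, phosphate and flower genes no member had a named probe set, so these lists were not analysed here. Proline, jasmonate, salicylate, circadian, guard cell and root lists had 1 or 2 named members and are given as values. The root genes fell under the filter. DREB2A, RD29A, RD29B, NCED3, P5CS1, PLC1, 5PTASE1, 5PTASE2 and MIPS2 were to be given in every comparison and are not analysed here, since no probe set is named for them in the annotation used. The transgene was not analysed here, so the labels of the transgenic arrays could not be checked against it.

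Genes were named by a rule fixed before the data were examined. For the WT day 7 change, the 2 transgenic comparisons and the difference between the day 7 changes, these were the 10 largest rises and 10 largest falls among called genes with 1 name, with the same sign in both transgenic lines where those were compared. For other comparisons the 3 largest in each direction were taken. From each list, up to 4 called members with the smallest adjusted p were named, and with fewer than 2 called, the members of largest absolute change as values. Genes named outside this rule are pointed out as chosen after their values were seen.

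The model was tested on simulated data with 15808 genes, of which 200 were changed, using each probe set's residual spread. For the WT day 7 change it recovered 78% of genes changed by 2 on the log2 scale and 20% of those changed by 1. For the mean of T6 and T8 against WT at day 7 the shares were 86% and 36%, for the well-watered comparison 82% and 40%, for the C2 change 66% and 10%, and for the difference between day 7 changes 74% and 16%. Of 107 simulated calls for the WT day 7 change 11 were false, and of 122 for the transgenic comparison at day 7, 8 were false. Noise was drawn independently for each gene, and the adjusted threshold depends on how many genes change. In the data, 5943 probe sets were called for WT, 2614 for C2, and 12 and 65 for the transgenic comparisons. The simulated shares hold for 200 changed genes and do not describe these comparisons.

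Alternatives fixed before the data were examined were quantile normalization, centring each array on its median, pseudocounts of 1 and 64, no filter and a filter at the 60th percentile, the replicate number as a block, no intensity trend, only the groups compared, the mean of WT and C2 as control, and each array left out in turn. Alternatives chosen after seeing the data were leaving out the 2 arrays with the highest 3' to 5' GAPDH control ratio, array quality weights, that ratio as a covariate, removal of the slope on the GAPDH, actin or UBQ ratio, leaving out the 3 arrays with the highest GAPDH ratio, every pairing of day 0 and day 7 arrays within a line, and splits of the arrays that keep the replicate number. Gene groups formed from the annotation after seeing the data are used only in the closing section. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

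No well-watered plants were sampled on day 7, so plant age and time changed together with water supply. The number of arrays, not a read depth, limits precision. Ratios of 3' to 5' GAPDH control probe sets ranged from 3.00 to 5.84 on the log2 scale, with a median of 3.59, and were highest on WT day 0 replicate 1 (5.84), T6 day 0 replicate 1 (4.59) and WT day 0 replicate 3 (4.45).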

Results

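Leaf transcript levels were compared between wild-type Arabidopsis (WT), a vector control line (C2) and 2 independent lines (T6 and T8) carrying an InsP 5-ptase transgene. Leaves were taken on day 0 from well-watered plants and on day 7 after water was withheld. By then, the labels put the relative water content of WT and C2 leaves at 50 to 60% and that of T6 and T8 leaves above 85%. WT, T6 and T8 had 3 independent replicate arrays per time point and C2 had 2. The first principal component, with 51.9% of the variance, separated day 0 from day 7. T6 day 7 replicate 1 (score -7.68) and T8 day 7 replicate 3 (10.01) lay nearest to the day 0 arrays, whose scores ran from -63.04 to -37.21, while WT day 7 arrays scored 60.04 to 99.02.

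The first question was what the water stress course changed in wild-type leaves. The largest estimated rises among named genes were those of AT1G05340, higher by 8.51 ± 1.32 (SE) on the log2 scale (n = 3 and 3 arrays), and AT3G02480, higher by 8.35 ± 0.92. LEA4-5, a late embryogenesis abundant protein that protects drying cells, went from 5.92 ± 0.67 to 12.8 ± 0.3 (SD, n = 3), a log2 change of 6.88 (adjusted p = 2.86e-06). AT3G17520 (6.86), AT5G50360 (6.64), AT1G09500 (6.41), the lysine-catabolic gene AT4G33150 (LKR/SDH, 5.82), AT3G57010 (5.79), AT5G44310 (5.73) and the drought-induced gene DI21 (5.61) completed the 10 largest rises. The defensin PDF1.2, a marker of jasmonate and ethylene signalling, fell by 6.49 ± 0.82 on the log2 scale, and its paralog PDF1.2b fell by 4.80. Other large falls were those of AT5G63180 (-5.91), AT5G22580 (-5.66), AT5G05250 (-5.46), AT5G03350 (-5.37), the expansin EXPA8 (-5.17), AT1G29660 (-5.14), AT1G72920 (-4.84) and AT5G59670 (-4.79). Every one of these 20 genes had non-overlapping day 0 and day 7 arrays in WT. For 12 of the 20, among them EXPA8 and all the raised ones except AT4G33150 and DI21, every array of the dimmer day lay below its own 40th percentile. Whether such signals exceed background is not known, so these sizes depend on the pseudocount and their order is not settled. With signals below that percentile set to it, the log2 change was at least 7.71 for AT1G05340, 6.15 for AT3G02480, 6.1 for LEA4-5 and 3.3 for EXPA8. In all, 5943 of 15808 probe sets were called, 2613 higher and 3330 lower. With each array centred on its median the split was 4004 higher and 2107 lower, because that scaling raised all WT changes by 0.27 on the log2 scale; the median change was -0.11 on the deposited scale and 0.15 after centring.

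Among the fixed lists, 5 of 6 measured LEA protein and dehydrin genes rose in WT and 1 fell. Besides LEA4-5, the dehydrins XERO2 (3.50 ± 0.40) and COR47 (1.95 ± 0.22) rose, and the chloroplast-targeted COR15B fell by 1.74 ± 0.28 on the log2 scale. COR15A, its neighbouring paralog, rose by 1.25 ± 0.21, and LEA18, which was dim on day 0, by at least 2.93 (4.89 ± 0.97 as fitted); these 2 genes were chosen after their values were seen. The list ranked higher than other genes (camera, adjusted p = 0.000874; adjusted p = 0.213 with an estimated correlation). All 5 flavonoid genes rose, led by the anthocyanin pathway enzymes UF3GT (3.97 ± 1.02) and DFR (3.86, adjusted p = 0.00995) (camera, adjusted p = 0.00823; adjusted p = 0.261 with an estimated correlation). All 8 photosynthesis genes fell, among them the light-harvesting gene LHCB4.3 (-2.48 ± 0.38), the photosystem genes PSBW (-1.51 ± 0.26) and PSBY (-2.76 ± 0.50), and LHCB4.1 (-1.62 ± 0.30) (camera, adjusted p = 9.8e-05; adjusted p = 0.23 with an estimated correlation). The counts adjusted over the list alone were the same for these 3 lists, with 5 higher and 1 lower, 5 higher, and 8 lower. Without WT day 0 replicate 2 the call of DFR ended (3.00, adjusted p = 0.056), as did those of 5MAT (2.26) and UGT78D2 (1.98). Without WT day 7 replicate 1, 5MAT (2.62) and UGT78D2 (2.26) missed the threshold, and without WT day 7 replicate 2 UGT78D2 (2.35) did.

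Of 6 phosphoinositide pathway genes, 3 rose and 1 fell in WT. PLC7, a phospholipase C that releases inositol phosphate from a membrane lipid, rose by 3.19 ± 0.25, the inositol phosphate kinase gene ITPK3 by 1.40 ± 0.30 and the inositol polyphosphate phosphatase gene FRA3 by 0.85 ± 0.18. VTC4, an inositol monophosphatase, fell by 1.72 ± 0.50 on the log2 scale. Adjusted over the list alone, 3 were higher and 2 lower, and the list as a whole did not pass (camera, adjusted p = 0.152). Of 3 senescence genes, SAG29 (5.52 ± 0.53) and WRKY6 (1.58 ± 0.48) rose and WRKY53 (-2.96 ± 1.02) fell (camera, adjusted p = 0.136). One of 5 heat shock genes rose, HSP26.5 (2.54 ± 0.73; list adjusted p = 0.196), while HSP17.6C had a value of 1.47 ± 0.67 that did not pass. Of 3 cell wall genes, EXPA8 and EXPA15 (-1.06 ± 0.29) fell (camera, adjusted p = 0.0675). Adjusted over the list alone, 2 senescence genes were higher and 1 lower, 1 heat shock gene was higher, and 2 cell wall genes were lower. In lists too small to test, the ornithine aminotransferase gene OAT rose by 1.81 ± 0.29, GI by 0.62 ± 0.17, and the guard-cell-expressed gene GC1 (-4.12 ± 0.45) and the salicylate-linked genes GRX480 (-2.13 ± 0.49) and SAG101 (-1.52 ± 0.30) fell. The dimmer day of HSP26.5, SAG29 and GC1 lay below the 40th percentile on all its arrays, and their log2 changes were at least 0.86, 4.84 and 3.51 by the bound above. PRODH2 (0.46 ± 0.53), THI2.1 (-0.29 ± 0.43) and the guard cell regulator FAMA (-0.43 ± 0.30) did not pass. The call of WRKY53 ended without WT day 0 replicate 1 (-2.61) or 3 (-2.17) and without WT day 7 replicate 1 (-2.99) or 2 (-2.70). That of WRKY6 ended without WT replicate 2 of day 0 or of day 7 (adjusted p = 0.0722 and 0.0897), and that of EXPA15 without WT day 0 replicate 2 (-0.77). The cell wall list passed without WT day 0 replicate 3 (adjusted p = 0.0227) or WT day 7 replicate 2 (adjusted p = 0.0469), and THI2.1 had a value of 0.17 without WT day 0 replicate 1.

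**Figure D1:**
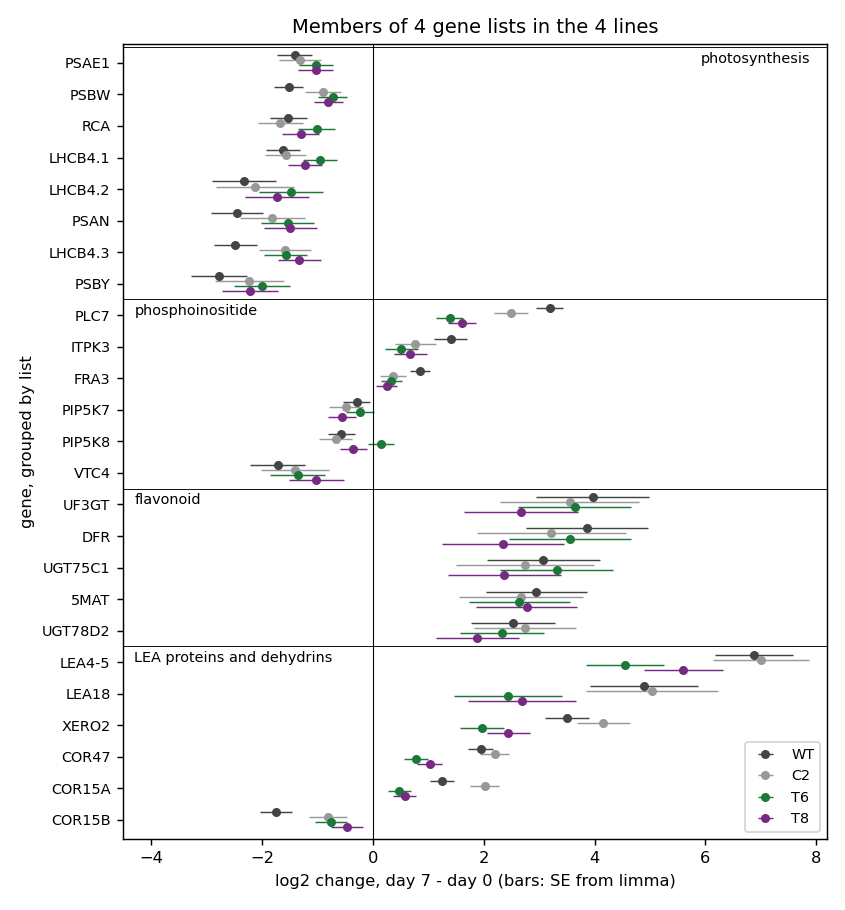
Log2 change from day 0 to day 7 (horizontal axis) of each measured member of 4 gene lists (vertical axis) in WT, C2, T6 and T8; points are limma estimates and bars their SE. LEA4-5 has the largest estimates, 6.88 in WT and 7.00 in C2, and COR15B lies below 0 in all 4 lines while COR15A lies above 0; in WT the value of COR15B was -1.71 under quantile normalization and -1.48 with arrays centred on the median.

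The vector control served as an additional control, and its leaves changed in the same direction as those of WT. AT1G05340 (8.36 ± 1.61), AT3G02480 (8.09 ± 1.12) and AT5G50360 (7.03 ± 0.78) rose the most in C2, and AT5G63180 (-6.06 ± 0.81), PDF1.2b (-5.26 ± 1.03) and EXPA8 (-4.95 ± 0.86) fell the most (n = 2 and 2 arrays). For 5 of these 6 genes, all but PDF1.2b, the dimmer day again lay below the 40th percentile on all its arrays. LEA proteins and dehydrins ranked higher in C2 too, with 5 of 6 members raised (camera, adjusted p = 2.34e-06; adjusted p = 0.033 with an estimated correlation). Photosynthesis genes ranked lower, 7 of 8 being called (camera, adjusted p = 0.000102; adjusted p = 0.194 with an estimated correlation). Flavonoid genes ranked higher (1 of 5 called, 5 adjusted over the list alone; adjusted p = 0.00649), as did heat shock (1 of 5 called, 1 adjusted over the list alone) and senescence genes (1 of 3 called, 2 adjusted over the list alone), and cell wall genes ranked lower (1 of 3 called, 1 adjusted over the list alone), all 3 at an adjusted p = 0.0313. With an estimated correlation these 4 lists had adjusted p-values from 0.194 to 0.22. Phosphoinositide genes did not pass (adjusted p = 0.37). C2 had 2614 called probe sets, 1194 higher and 1420 lower, or 1524 and 874 with arrays centred on the median. Of these, 1112 were also higher and 1277 also lower in WT, where independent lists would share 197.4 and 299.1, and 0 were opposite. Across all probe sets, which are not independent replicates, the 2 changes correlated with r = 0.882. The C2 count depended on single arrays, being 1285 without C2 day 7 replicate 1, 669 without C2 day 7 replicate 2 and 467 without C2 day 0 replicate 2. PDF1.2b missed the threshold without C2 day 7 replicate 2 (-3.70, adjusted p = 0.072). In each of these fits the lone remaining array is assumed to vary like those of the other groups.

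The next question was how the transgenic lines changed over the same course. In T6, AT5G50360 (5.29 ± 0.63), AT1G05340 (4.83 ± 1.32) and AT3G53980 (4.59 ± 0.68) rose the most, and PDF1.2b (-5.59 ± 0.84), PDF1.2 (-5.04 ± 0.82) and AT5G03350 (-4.77 ± 1.15) fell the most. In T8, AT1G05340 (6.41 ± 1.32), AT5G50360 (6.02 ± 0.63) and AT3G02480 (5.95 ± 0.92) led the rises, and AT5G03350 (-6.35 ± 1.15), PDF1.2 (-5.84 ± 0.82) and PDF1.2b (-4.85 ± 0.84) the falls. The 3 raised genes of T8 were below the 40th percentile on all its day 0 arrays. AT1G05340 varied widely between T6 day 7 replicates, at 10.1 ± 4.0 (SD, n = 3), and its day 0 and day 7 arrays overlapped in T6. T6 had 1725 called probe sets (913 higher, 812 lower) and T8 had 1863 (874 higher, 989 lower; 1147 and 760 with arrays centred on the median). The 2 lines shared 588 higher and 608 lower probe sets, against 50.5 and 50.8 for independent lists, with 0 opposite. With WT, T6 shared 772 higher and 763 lower probe sets and 1 went opposite; T8 shared 775 and 915 with 0 opposite. LEA proteins and dehydrins ranked higher in T6, with 3 of 6 called (camera, adjusted p = 0.0072; adjusted p = 0.238 with an estimated correlation), and in T8, with 3 of 6 called (adjusted p = 0.00038; adjusted p = 0.132 with an estimated correlation). Adjusted over the list alone, 5 members were higher in both lines, and 1 was lower in T6. Photosynthesis genes ranked lower, 4 of 8 being called in T6 and 6 in T8, and 8 in each adjusted over the list alone (camera, adjusted p = 1.11e-05 in T6 and 1.18e-05 in T8; 0.238 and 0.167 with an estimated correlation). Flavonoid genes ranked higher in T6 (3 of 5 called; camera, adjusted p = 0.00214) and T8 (0 of 5 called; 0.00838), with 5 higher in each adjusted over the list alone (0.238 and 0.342 with an estimated correlation). Cell wall genes ranked lower in T8 (1 of 3 called, 2 adjusted over the list alone; adjusted p = 0.0176; 0.132 with an estimated correlation) but did not pass in T6 (0.0916). The heat shock, phosphoinositide and senescence lists did not pass in either line, with adjusted p-values from 0.167 to 0.694.

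The T6 and T8 counts also depended on single arrays. The T6 count was 620 without T6 day 0 replicate 1, 774 without day 0 replicate 3, 380 without day 7 replicate 2 and 658 without day 7 replicate 3. A fit of the T6 arrays alone called 66. In T6 the call of AT1G05340 ended without day 0 replicate 1 (4.46) or 2 (4.43) and without day 7 replicate 2 (2.90) or 3 (4.72), and that of AT5G03350 without day 0 replicate 1 (-4.39) or day 7 replicate 2 (-3.29). The T8 count was 1042 without T8 day 0 replicate 1, 697 without day 0 replicate 3, 831 without day 7 replicate 1 and 419 without day 7 replicate 2.

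Probe sets called in C2, whose arrays are in neither side of this test, changed less in T6 and T8 than in WT. By the labels C2 leaves had the water content of WT leaves, so this choice favours probe sets that respond at that water loss. No choice from T6 or T8 was run. Over the 2614 probe sets, the median change in the direction seen in C2 was 1.47 ± 0.39 in WT, 0.85 ± 0.30 in T6 and 0.91 ± 0.27 in T8 (SD, n = 3 array pairs each). The mean of T6 and T8 was 59.5% of the WT value, a difference of -0.60 (two-sided exact permutation p = 0.0238, 84 splits). For the 1194 probe sets that rose in C2 the difference was -0.67 (exact permutation p = 0.0119, the smallest these splits allow), and for the 1420 that fell it was 0.56 (exact permutation p = 0.0476). Day 0 and day 7 arrays share only a number, so all 216 pairings of them within the lines were run after the result was seen. The difference lay between -0.61 and -0.58, with an exact permutation p from 0.0119 to 0.0714 that was under 0.05 in 178 of the 216 pairings, 208 for the part that rose and 109 for the part that fell. T6 alone against WT gave an exact permutation p = 0.1, the smallest possible with 3 against 3, and T8 alone 0.2. WT replicate 2 had the largest value, 1.91, and number 2 was also the highest in T6 (1.14) and in T8 (1.18). With arrays centred on the median, the part that fell gave 0.41 (exact permutation p = 0.202). The difference was -0.36 without WT day 0 replicate 2 or WT day 7 replicate 2 (exact permutation p = 0.107 for both). It lay between -0.67 and -0.52, with an exact permutation p between 0.0536 and 0.0714, without any one of WT day 7 replicate 1, T6 day 0 replicates 1 and 3, T6 day 7 replicates 1 and 3, T8 day 0 replicates 1 and 3, and T8 day 7 replicates 1 and 3.

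**Figure D2:**
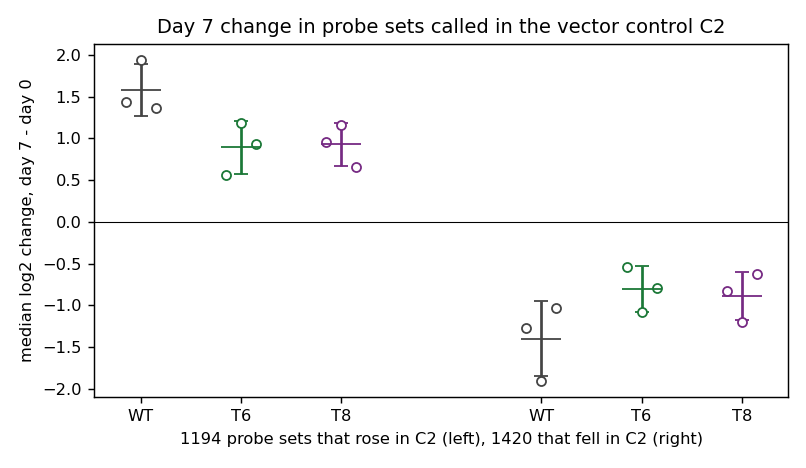
Median log2 change from day 0 to day 7 (vertical axis) over the 1194 probe sets that rose and the 1420 that fell in C2, for WT, T6 and T8 (horizontal axis). Circles are array pairs of the same number, and bars are the mean ± SD of 3 pairs; the rising set averages 1.58 in WT, 0.89 in T6 and 0.93 in T8.

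Before water was withheld, the transgenic lines were compared with WT to see what the transgene itself altered. PLC7 was higher in both lines, at 9.32 ± 0.47 in T6 and 9.46 ± 0.07 in T8 against 8.21 ± 0.25 in WT (SD, n = 3) and 8.33 ± 0.26 in C2 (n = 2). The difference from WT was 1.18 ± 0.21 (SE), or 2.27-fold (adjusted p = 0.0342). The 4 named genes that were lower were the putative chitinase gene AT2G43570 (-2.43 ± 0.38, 5.37-fold), SAL2, a homolog of an inositol polyphosphate and nucleotide phosphatase (-2.12 ± 0.33), the triterpene synthase gene LUP5 (-2.03 ± 0.30) and AT3G60540 (-1.45 ± 0.27). AT2G43570 stood at 10.58 ± 0.39 in WT and 11.96 ± 0.18 in C2, but at 8.21 ± 0.95 in T6 and 8.10 ± 0.31 in T8. The T6 and T8 arrays overlapped those of WT for AT3G60540 and for no other of these 5 genes. In all, 12 probe sets were called, 1 higher and 11 lower, and 3 of them were also called lower at day 7.

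Among the lists, LEA proteins and dehydrins ranked higher in well-watered T6 and T8 leaves, although 0 of 6 members were called over all probe sets (2 higher adjusted over the list alone; camera, adjusted p = 0.00586; adjusted p = 0.159 with an estimated correlation). COR47 had a difference of 0.72 ± 0.19 (adjusted p = 0.26) and XERO2 of 0.80 ± 0.34. Phosphoinositide genes also ranked higher, with PLC7 the 1 member called (camera, adjusted p = 0.0196; adjusted p = 0.159 with an estimated correlation). The other 5 lists did not pass, with camera adjusted p-values from 0.139 for heat shock to 0.69 for photosynthesis, and 1 heat shock gene was lower adjusted over the list alone. Other members had values of 0.81 ± 0.95 for DFR, -1.46 ± 0.61 for EXPA8, -1.15 ± 0.89 for WRKY53, -0.84 ± 0.26 for SAG101, -0.82 ± 0.46 for PRODH2 and -0.67 ± 0.30 for HSP15.7, none of them called. The LEA list missed the threshold without WT day 0 replicate 2 (adjusted p = 0.0643), and the phosphoinositide list without WT day 0 replicate 1 (0.157) or T8 day 0 replicate 2 (0.0631). Without WT day 0 replicate 1 the flavonoid list passed (0.0441), without replicate 2 the heat shock list (0.0458) and the call of SAG101 (-1.23), and without replicate 3 the cell wall list (0.0414).

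The count of 12 rested on few arrays. PLC7 missed the threshold without WT day 0 replicate 1 (1.07) or 3 (1.16), T6 day 0 replicate 2 (1.05) and T8 day 0 replicate 1, 2 or 3 (adjusted p from 0.0583 to 0.109). AT2G43570, SAL2 and LUP5 missed it without WT day 0 replicate 1 (-2.21, -1.99 and -1.96) or 3 (-2.51, -2.01 and -2.04). AT3G60540 missed it without any one of these arrays except WT day 0 replicate 2 and T6 day 0 replicate 1, at -1.53 to -1.24. The count was 0 without WT day 0 replicate 1, 1 without replicate 3 and 66 without replicate 2 of the same group, 48 and 7 without T6 day 0 replicates 1 and 2, and 7 without T8 day 0 replicate 1. A fit of the well-watered groups alone called 0, and WT and C2 together as control gave 86. WT day 0 replicate 1 and T6 day 0 replicate 1 had the highest 3' to 5' ratios of the GAPDH control (5.84 and 4.59 on the log2 scale), and with that ratio as a covariate the count was 0.

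**Figure D3:**
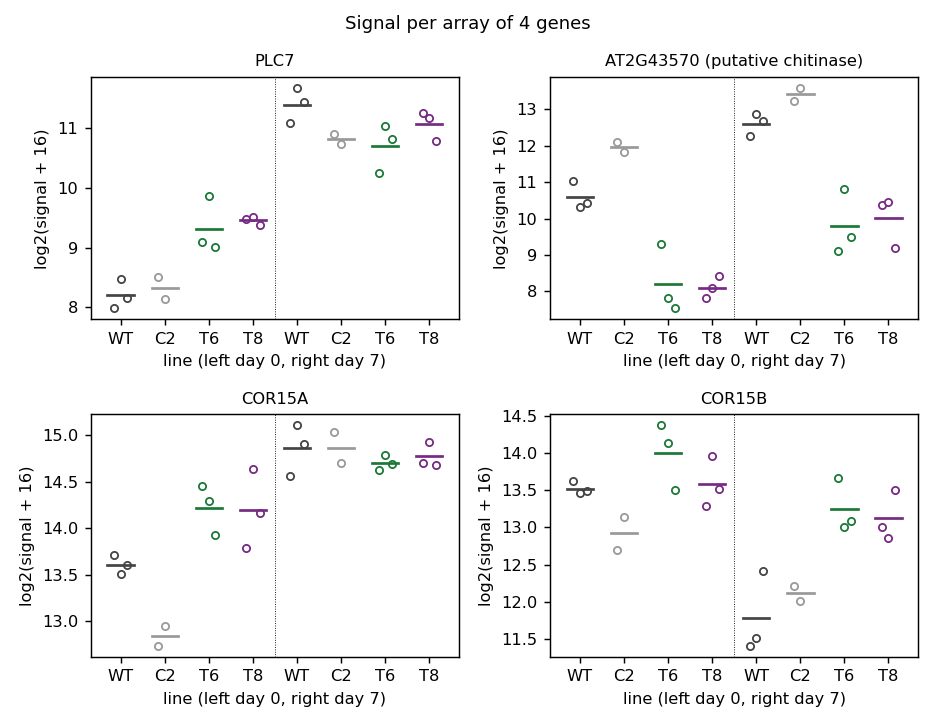
log2(signal + 16) (vertical axes) of PLC7, AT2G43570, COR15A and COR15B on each of the 22 arrays by line (horizontal axes), day 0 left and day 7 right of the dotted line; circles are arrays and bars group means. On day 0, PLC7 averages 9.32 in T6 and 9.46 in T8 against 8.21 in WT, and AT2G43570 averages 8.21 and 8.10 against 10.58.

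At day 7 the transgenic lines were set against WT at the same time, when the labels also put their leaf water content higher. AT2G43570 was again lower, at 9.80 ± 0.89 in T6 and 10.0 ± 0.7 in T8 against 12.61 ± 0.31 in WT (SD, n = 3), a log2 difference of -2.70 ± 0.38 (SE; adjusted p = 0.0133). The alpha-amylase gene AMY1 was lower by a log2 difference of -1.50 ± 0.26 (2.84-fold). COR15B was higher by 1.41 ± 0.25 (2.65-fold), at 13.25 ± 0.36 in T6 and 13.12 ± 0.34 in T8 against 11.78 ± 0.55 in WT. The gibberellin receptor gene GID1A was higher by 1.12 ± 0.24 and MENG, a phylloquinone biosynthesis gene, by 1.15 ± 0.21. Other higher genes were AT4G00980 (1.94), AT5G36270 (1.81), AT5G66520 (1.57), AT2G48030 (1.56), AT3G06770 (2.46-fold), AT5G41460 (1.08) and AT2G33170 (1.01). Lower genes included AT5G43770 (-2.62), AT1G24600 (-2.38), AT3G15760 (-2.31), AT4G00700 (-2.02), AT1G02470 (-1.49), AT3G03270 (-1.35), AT3G57020 (-1.33) and AT4G32250 (-1.33). T6 or T8 arrays overlapped those of WT for AT1G24600, AT3G15760 and AT3G03270. AT4G00980, AT5G36270, AT5G66520 and AT2G48030 were below the 40th percentile on all 3 WT arrays, and AT5G43770 on all 6 transgenic ones. For AT5G43770, with 0 of 3 WT arrays below it, the log2 difference was at least 1.63 in size by the bound above. For the others the brighter side was partly or wholly below it too. This held on 3 of 6 transgenic arrays for AT4G00980 and AT5G36270, 4 of 6 for AT2G48030 and 6 of 6 for AT5G66520. No bound can be given for these genes, and AT5G66520 has no size that can be read.

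In all, 65 probe sets were called at day 7, 27 higher and 38 lower in the transgenic lines, and all 65 had the same sign in T6 and T8. Picking on the mean of both lines against the same WT arrays largely sets that agreement. Median centring gave 20 higher and 162 lower, since it lowered all differences by 0.12 on the log2 scale. In sign, the 65 mostly opposed the course seen in C2. Of the 27 higher probe sets, 25 had a negative estimate in C2, and of the 38 lower ones 36 had a positive one, where 56.2% and 43.8% of all probe sets tested were negative and positive. These are signs of the C2 estimates, and 37 of the 65 were called in the C2 change. Single lines against WT gave fewer calls, 0 for T6 and 1 for T8. The count without 1 array was 186, 0 and 194 for WT day 7 replicates 1, 2 and 3, 3, 1175 and 2 for T6 replicates 1, 2 and 3, and 1, 441 and 1 for T8 replicates 1, 2 and 3. AT2G43570 missed the threshold without WT day 7 replicate 2 (-2.57, adjusted p = 0.203). COR15B missed it without that array (1.27) and without replicates 1 and 3 of T6 or of T8 at day 7 (adjusted p from 0.0574 to 0.086). A fit of the day 7 groups alone called 0, WT and C2 together as control gave 1068, and the replicate number as a block gave 417.

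Photosynthesis genes ranked higher in the transgenic lines at day 7 (0 of 8 called, 1 higher adjusted over the list alone; camera, adjusted p = 0.00905; adjusted p = 0.493 with an estimated correlation). LHCB4.3 had a 2.14-fold difference (adjusted p = 0.0859). Heat shock genes ranked lower (0 of 5 called, 1 lower adjusted over the list alone; camera, adjusted p = 0.00961; adjusted p = 0.218 with an estimated correlation), with HSP26.5 at -2.44 ± 0.63. Senescence genes also ranked lower (0 of 3 called, 2 lower adjusted over the list alone; camera, adjusted p = 0.0118; adjusted p = 0.218 with an estimated correlation), with SAG29 at -1.47 ± 0.46 and WRKY6 at -1.40 ± 0.41. LEA proteins and dehydrins did not pass (camera, adjusted p = 0.166), with COR15B the 1 member called; adjusted over the list alone 1 was higher and 2 lower. Flavonoid genes did not pass either, with a median of -0.09 and 0 of 5 called (camera, adjusted p = 0.696), UF3GT having a difference of -0.34 ± 0.88. The same held for phosphoinositide (adjusted p = 0.415) and cell wall genes (adjusted p = 0.744).

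Whether the day 7 change itself differed between transgenic lines and WT was tested as an interaction. No probe set passed in limma (0 called, 2154 at an unadjusted p under 0.05). LEA proteins and dehydrins ranked lower in this difference (median -1.17, 0 of 6 called, 3 lower and 1 higher adjusted over the list alone; camera, adjusted p = 0.00662; adjusted p = 0.188 with an estimated correlation). LEA18 had a value of -2.33 ± 1.19 and LEA4-5 of -1.80 ± 0.86. Phosphoinositide genes ranked lower too (0 of 6 called, 1 lower adjusted over the list alone; camera, adjusted p = 0.0368; adjusted p = 0.188 with an estimated correlation). PLC7 had changed by 3.19 ± 0.25 in WT, 2.49 ± 0.30 in C2, 1.39 ± 0.25 in T6 and 1.61 ± 0.25 in T8, an interaction of -1.69 ± 0.30 (adjusted p = 0.184). Photosynthesis genes ranked higher (0 of 8 called; camera, adjusted p = 0.0368; adjusted p = 0.479 with an estimated correlation). The other 4 lists did not pass, with camera adjusted p-values from 0.163 to 0.249. Leaving out WT day 0 replicate 2 gave 1 called probe set, and leaving out T6 day 7 replicate 2 gave 4, among them PLC7 (-1.78, adjusted p = 0.0417). The phosphoinositide list missed the threshold without WT day 0 replicate 1 (0.0933), WT day 7 replicate 2 (0.0533) or 3 (0.0651), T6 day 7 replicate 2 (0.072), T8 day 0 replicate 2 (0.0611) or T8 day 7 replicate 2 (0.0721). The photosynthesis list missed it without WT day 0 replicate 1 (0.0933) or 2 (0.093), WT day 7 replicate 1 (0.12) or 2 (0.194), T6 day 0 replicate 2 (0.0756), T6 day 7 replicate 1 (0.151) or 3 (0.0629), T8 day 0 replicate 2 (0.0611) or T8 day 7 replicate 3 (0.135). The senescence list passed without WT day 0 replicate 3 (0.0472).

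Controls for the line comparisons gave no calls. C2 against WT had 0 called probe sets when well watered (723 at an unadjusted p under 0.05), 0 at day 7 (550) and 0 for the difference between their day 7 changes (397), all in limma. Without C2 day 7 replicate 1 the day 7 count was 8. LEA proteins and dehydrins ranked lower in well-watered C2 than in WT (camera, adjusted p = 0.00839; adjusted p = 0.36 with an estimated correlation), the opposite side of WT from T6 and T8. T6 against T8 had 0 called probe sets when well watered (343 at an unadjusted p under 0.05) and 0 at day 7 (185), and neither count changed when any 1 of their arrays was left out. The C2 counts rest on 2 C2 arrays per time, so they cannot be set beside counts from the mean of T6 and T8. Against WT, single lines gave 1 call for T6 (792 at an unadjusted p under 0.05) and 9 for T8 (1422) when well watered. At day 7 they gave 0 for T6 (2682) and 1 for T8 (2177).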

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

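The tests of signal scale and of RNA quality were chosen after the result was seen; the splits into 3 groups of 3 were also chosen after 2 other forms of that count had been seen, and the splits that keep the replicate number and the other pairings of arrays were chosen last.

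The day 7 change of probe sets called in C2 was picked out because T6 and T8 differed from WT by a test of the difference itself (-0.60, exact permutation p = 0.0238; 178 of 216 pairings of day 0 with day 7 arrays gave a p under 0.05). A compressed signal scale on the transgenic arrays is argued against, since quantile normalization, which gives every array 1 distribution, left a difference of -0.58 (exact permutation p = 0.0357). Poor RNA on the 2 day 0 arrays of highest 3' to 5' GAPDH ratio is argued against as the whole cause, because the difference without them was -0.57 (exact permutation p = 0.0476). WT day 0 replicate 3, whose ratio comes next (4.45), stays in that test. The 3' to 5' ratio of GAPDH went from 4.61 to 3.70 in WT, and that of the actin control from 4.74 ± 0.52 to 5.89 ± 0.62 in WT, 5.26 ± 0.41 to 5.51 ± 0.23 in T6, 5.12 ± 0.25 to 5.78 ± 0.14 in T8 and 5.09 ± 0.59 to 5.54 ± 0.13 in C2 (SD). As the whole cause these ratios are argued against too: with the slope on each within groups removed, the difference was -0.68 for GAPDH, -0.61 for actin and -0.56 for UBQ (exact permutation p = 0.0119, 0.0238 and 0.0476). What stays open is leaf water content, which the labels put above 85% in T6 and T8 and at 50 to 60% in WT and C2: 0 transgenic groups were harvested at the wild-type water content, so a weaker response to a given water loss and a smaller water loss cannot be told apart. The weight of WT replicate 2, without either array of which the difference was -0.36 (exact permutation p = 0.107), also limits the result. That value keeps number 2 of T6 (1.14) and T8 (1.18), the highest of each line. If the numbers mark a shared structure, which the labels do not say, leaving number 2 out of WT alone shrinks the difference.

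The LEA protein and dehydrin, phosphoinositide and photosynthesis lists were picked out because their day 7 change differed between the transgenic lines and WT in the interaction test, with camera adjusted p-values of 0.00662 for LEA proteins and dehydrins, 0.0368 for phosphoinositide genes and 0.0368 for photosynthesis genes. None of these lists passed with an estimated correlation (adjusted p = 0.188, 0.188 and 0.479) or with fry (adjusted p = 0.0834, 0.0834 and 0.309).

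Counts over other splits of the same arrays limit the comparisons between lines. For the well-watered comparison of T6 and T8 with WT, the real grouping gave 12 probe sets, 13 of 100 drawn splits into 3 groups of 3 gave as many, and the highest other gave 1107, so chance cannot be excluded. The 4 splits with the most calls, 1034 to 1107, all put WT day 0 replicates 1 and 3 with T6 day 0 replicate 1, which points to a structure of the arrays that the lines do not explain. These 3 arrays have the highest 3' to 5' GAPDH ratios of all 22 (5.84, 4.45 and 4.59) and the highest 25S rRNA signals, but actin ratios among the lowest (4.75, 4.22 and 5.01). At day 7 the real grouping gave 65, and 5 of 100 splits gave as many, the real one included. Of the 5, 1 with 165 calls kept the WT arrays together and exchanged only T6 and T8 arrays. It leaves the difference from WT as it is, so it says nothing about chance. The rest moved WT arrays and gave 111, 171 and 1632, the last with T6 replicates 1 and 3 and T8 replicate 3 on one side. Whether the share is small enough to exclude chance turns on counting the split with 165 calls, so chance was left undecided. That verdict depended on the form of the fit: with T6 and T8 merged, the real day 7 grouping gave 340 and 3 of 84 splits gave as many, and with the day 7 groups alone it gave 0 and 7 of 84 splits gave more. The well-watered comparison gave 11 with T6 and T8 merged, with 8 of 84 splits as large, and 0 with its groups alone, with 4 of 84 giving more. These splits ignore the replicate number, which same-day arrays of different lines may share as a structure: in 16 of 16 same-day pairs of WT with another line, arrays of 1 number correlated above 0 (0.007 to 0.418). Over all same-day pairs, those without WT included, 26 of 30 were above 0 and the lowest was -0.186. Among 100 splits that kept the numbers, in the fit with the number as a block, 4 gave as many as the real 417 at day 7 (highest other 706) and 4 as many as the real 13 when well watered (highest other 25). These 4 are the real split and 3 that only exchange T6 and T8 arrays, which leave the difference from WT as it is. The 96 splits that moved a WT array gave at most 2 at day 7 and 7 when well watered, which goes against chance if the numbers mark a shared structure. The labels do not say so, and this form was run last, so the comparisons stay undecided. The interaction gave 0, so all 100 splits had to give as many and their count decides nothing; the highest other split gave 390.

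For 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The WT day 7 change gave 5943 for the real split and 1 at most for the others (1 of 10 splits as large), T6 gave 1725 and 1 (1 of 10), and T8 gave 1863 and 0 (1 of 10). T6 against T8 gave 0 when well watered, with 33 at most for the others, and 0 at day 7, with 363 at most; all 10 splits gave as many in both.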

How the results depend on the processing

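Array quality weights, leaving out the 2 arrays of highest GAPDH ratio, that ratio as a covariate, the slopes, the 3 arrays and the pairings were chosen after the results were seen. Precision is limited by 2 or 3 arrays per group, and for dim probe sets by signal over background. Named genes gave 1849 values counted as unchanged under alternatives other than single left-out arrays. Another 100 missed the threshold, 18 passed it newly and 9 had the opposite sign. With single arrays left out these were 1266, 146, 12 and 1. Values for lists were 329, 13, 7 and 0, and with single arrays left out 270, 18, 6 and 0. A gene called in neither fit also counted as unchanged when its sign turned by less than its SE. A list that passed in neither fit counted as unchanged whichever way it ranked, so the 0 for lists does not cover these. The smaller day 7 change of C2-called probe sets in T6 and T8 kept its sign and threshold under most alternatives run (-0.66 to -0.54). That range leaves out single left-out arrays, the 3 left-out arrays, other pairings of arrays and removed slopes. Of 216 pairings, 178 had a p under 0.05. With the slope on the GAPDH, actin or UBQ ratio removed it was -0.6754, -0.6123 and -0.5588. Without the 3 arrays of highest GAPDH ratio it was -0.9727, but the WT value (1.91) then rests on pair 2 alone. Whether the difference passes the threshold cannot be judged from that. The fit of compared groups alone and weights gave no value for it. Its parts are different: the fall missed the threshold under quantile normalization, median centring and the 60th percentile filter.

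The count for T6 and T8 against WT at day 7 (65) was 19 with quantile normalization, 182 with arrays centred on the median, 162 with a pseudocount of 64, 20 without a filter, 195 with a filter at the 60th percentile, 24 without an intensity trend, 0 with only the groups compared (fewer residual degrees of freedom) and 1068 with the mean of WT and C2 as control. It was 123 without the 2 arrays of highest GAPDH ratio, 1716 with array quality weights and 264 with the GAPDH ratio as a covariate. When well watered (12), the count was 0 with only the groups compared, 86 with the mean of WT and C2 as control and 0 with the covariate. The T6 change (1725) gave 66 with only the groups compared, 750 without the 2 arrays and 3232 with weights; weights also gave 4102 for C2 (2614) and 4617 for T8 (1863). C2 against WT at day 7 (0) gave 1 without the 2 arrays and 1 with weights. T6 against T8 (0) gave 1 when well watered with a pseudocount of 1, and 140 at day 7 with weights. Except where stated, the cause was not tested.

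Lists passing numbered 3 for the WT change, 2 and 3 for T6 and T8 against WT when well watered and at day 7, and 3 for the interaction. With an estimated inter-gene correlation these were 0, 0, 0 and 0. None of the lists that passed camera for T6 and T8 against WT or in the interaction passed fry. Adjusted fry p-values were 0.103 (LEA) and 0.0814 (phosphoinositide) when well watered, and 0.113 (photosynthesis), 0.0701 (heat shock) and 0.0701 (senescence) at day 7. In the WT change fry passed every list except heat shock (adjusted p = 0.0872). These include phosphoinositide (0.00045), senescence (0.00105) and cell wall genes (0.000191), which did not pass camera. Fry also passed lists that missed camera in the T6 change, cell wall (0.0254) and senescence (0.0326), and in the T8 change, senescence (0.0311). Flavonoid genes passed camera but missed fry in C2 (0.0504) and T8 (0.0639). The LEA list in well-watered C2 against WT missed fry too (0.523). The WT number was 6 with the covariate. The well-watered number was 1 with the mean of WT and C2 as control, 1 with weights and 1 with the covariate. The interaction number was 1 with the mean of WT and C2 as control, 1 without the 2 arrays and 1 with weights. The cause was not tested.

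Values counted as of opposite sign all belong to genes that were not called. With the mean of WT and C2 as control, PSBW was 0.0737 when well watered and THI2.1 -0.1121 at day 7. The WT change of THI2.1 ran from -0.5957 without WT day 0 replicate 3 to 0.1749 without WT day 0 replicate 1, and was 0.1749 without the 2 arrays of highest GAPDH ratio and 0.1573 with the covariate. The interaction value was -0.3043 for PRODH2 without the 2 arrays and -0.0098 for PDF1.2 with weights. With the covariate, the well-watered differences of PSBW, WRKY6 and FAMA were 0.0916, 0.1341 and 0.2318. The cause was not tested.

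With single arrays left out, counts ran from 4135 to 5614 for the WT change, 467 to 1876 for C2, 380 to 2545 for T6, 419 to 2238 for T8, 0 to 66 and 0 to 1175 for T6 and T8 against WT when well watered and at day 7, 0 to 4 for the interaction, and 0 to 8 for C2 against WT at day 7. They were 0 to 0 for C2 against WT when well watered, the C2 interaction and T6 against T8 at both times. The difference in C2-called probe sets ran from -0.8666 to -0.3622. Lists passing ran from 3 to 4, 1 to 3, 3 to 3 and 1 to 4 in the order above.

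The replicate numbers were not taken to pair the arrays, since same-number correlations were not all over 0.1 between WT and both transgenic lines on either day. Over all pairs they ran from -0.222 to 0.577. Pairs within a day had a median of 0.141 and 17 of 30 over 0.1, pairs of day 0 with day 7 a median of 0.007 and 3 of 41. WT and T6 on day 0 had all 3 over 0.1 (0.226 to 0.375), and 16 of 22 arrays correlated best with arrays of their own number, a hint from the data. With the replicate number as a block, the count for T6 and T8 against WT was 417 at day 7 and 13 when well watered, 2 for C2 against WT at day 7, 0 for the interaction and 6205 for WT; no other count moved by over 1.5 times. HSP26.5 (-2.44) was the 1 named gene whose call changed, passing against WT at day 7.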

Other observations

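All tests of explanations in this part were chosen after the results were seen, as were the 35 gene groups formed from the annotation and tested beside the fixed lists. Of 245 tests of these groups over 7 comparisons, 12 passed, and 0 with an estimated correlation.

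Of 8 measured autophagy (ATG) genes, which build the membrane that engulfs cell contents, 4 were called higher at day 7 in WT, with ATG8H at 3.34, ATG8B at 1.75, ATG3 at 1.55 and ATG8G at 0.74 (camera, adjusted p = 0.0121; adjusted p = 0.574 with an estimated correlation). In C2, 4 were higher, ATG8H by 3.77 and ATG8C by 1.17 among them (adjusted p = 0.0013; adjusted p = 0.56 with an estimated correlation), and in T8 4 were higher (adjusted p = 0.0104; adjusted p = 0.699 with an estimated correlation). In T6, 0 of 8 were called and the group did not pass (adjusted p = 0.12). At day 7 the group ranked lower in the transgenic lines than in WT, with 0 of 8 called and ATG8H at -2.04 (adjusted p = 0.00161; adjusted p = 0.646 with an estimated correlation). IQD genes, which encode calmodulin-binding proteins, ranked lower in C2 at day 7 with 4 of 9 called, IQD22 (-2.16) and IQD28 (-1.40) among them (adjusted p = 0.0391; adjusted p = 0.56 with an estimated correlation). This group did not pass in WT (5 of 9 lower, adjusted p = 0.166), T6 (1 lower, 0.307) or T8 (2 lower and 1 higher, 0.326). The other groups that passed did so in 1 comparison each: VPS genes ranked higher in C2 at day 7 (3 of 8 called, adjusted p = 0.031; adjusted p = 0.56 with an estimated correlation), PDF genes, which share a symbol for defensins and peptide deformylases, ranked lower in T6 (3 of 5 called, adjusted p = 0.00848; adjusted p = 0.736 with an estimated correlation), and UGT genes ranked lower in the transgenic lines than in WT at day 7 (0 of 33 called, adjusted p = 0.0124; adjusted p = 0.646 with an estimated correlation).

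Transcripts of 68 genes of the plastid genome ranked lower at day 7 in WT, with 31 called lower and 0 higher (median -0.74; camera, adjusted p = 8.96e-05; adjusted p = 0.574 with an estimated correlation). They also ranked lower in C2 (3 called, adjusted p = 0.00642; 0.856 with an estimated correlation) and T6 (5 called, 9.36e-09; 0.736), but did not pass in T8 (1 called, 0.118). Their mean log2 signal was 12.1 ± 0.53 on day 0 and 11.3 ± 0.12 on day 7 in WT, 11.72 ± 0.19 and 11.18 ± 0.15 in C2, 12.24 ± 0.23 and 11.72 ± 0.27 in T6, and 11.89 ± 0.43 and 11.68 ± 0.32 in T8 (SD, n = 3, or 2 in C2). Against WT at day 7 the group ranked higher in T6 and T8, with 0 of 68 called (median 0.34; adjusted p = 0.00136; adjusted p = 0.707 with an estimated correlation). WT day 0 replicates 1 and 3 and T6 day 0 replicate 1 had the highest GAPDH ratios and 25S rRNA signals of all arrays. Whether RNA quality or labelling entered the plastid signals was not tested, so a change in transcript amount is not established.

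The 12 probe sets that differed in well-watered T6 and T8 had a median difference from WT of 2.00 ± 0.42 (SD over probe sets) in their own direction. Odd WT arrays are argued against: compared with the same WT arrays, C2 had a median of -0.63 ± 0.46, on the other side of WT. Transformation or the vector as such is argued against, since 2 of the 12 had the transgenic sign in C2. Whether poor RNA on the 2 day 0 arrays of highest 3' to 5' GAPDH ratio is the whole cause was not decided. Without them the median was 2.03 ± 0.44, with 7 of the 12 still called. The 12 were picked for a large difference over a small spread on all these day 0 arrays. That choice largely keeps their median when some of the arrays are left out. WT day 0 replicate 3, whose ratio comes next (4.45), stays in that test. Without all 3 the median was 1.81 and 0 of the 12 were called, the median SE growing from 0.33 to 0.47 with 1 WT array left, so poor RNA on all 3 and a difference between the lines cannot be told apart. As a covariate, the GAPDH ratio gave a median of 1.77 with 0 called (SE 0.39) and the actin ratio 1.90 with 5 called (SE 0.36). The UBQ ratio gave 2.00 with 8 called. The same choice of probe sets limits these values, so all 3 ratios stay open. Besides, 13 of 100 splits that ignore the replicate number gave as many calls; of 100 that keep it, 4 did, all with the 3 WT arrays together.

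COR15A and COR15B, neighbouring genes for closely related chloroplast proteins, went opposite ways at day 7 in WT (1.25 and -1.74, both called). In C2 only COR15A was called (2.02; COR15B -0.81, adjusted p = 0.121), and in T6 (0.48 and -0.75) and T8 (0.58 and -0.46) neither was. Adjusted over the list alone, 5 members were higher and 1, COR15B, lower in C2 and in T6, so both passed there, while in T8 5 were higher and 0 lower. Cross-hybridisation between their probe sets is argued against in WT, since a shared signal moves both the same way and 1.25 ± 0.21 (SE) and -1.74 ± 0.28 have opposite signs beyond their spread. The same held in C2 and T6 with the list-alone adjustment, and T8 was not decided. Poor RNA on the 2 arrays of highest 3' to 5' GAPDH ratio is argued against for COR15B in WT, since it still changed by -1.69 without them. WT day 0 replicate 3, whose ratio comes next (4.45), stays in that test, which did not cover COR15A. An error in the probe set annotation was not tested, and neither was a biological explanation.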
